A study of Homo sapiens with 5 samples.

How the data were processed

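Nascent transcription was measured by PRO-seq (precision run-on sequencing) in HUDEP-2 cells, an immortalised human erythroid progenitor line. In this assay engaged RNA polymerases in isolated nuclei are allowed to incorporate biotin-labelled nucleotides, and the labelled RNA is captured and sequenced. The series holds 5 libraries, 2 of unedited cells and 3 of single-cell clones edited with the guide sg1617 in the BCL11A enhancer. The clones carried an insertion of 1 bp, a deletion of 13 bp and a deletion of 15 bp, with 1 library each.

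The values analysed here come from 2 deposited lists of called transcription start sites, 1 per strand, which were deposited for the series as a whole and have no column per library. Per the file headers, the calls were made with TSScall, a program that calls start sites from the 5′ ends of nascent RNA, on 1 sorted and de-duplicated alignment of HUDEP-2 cells. That alignment's name carries no edit and ends in a 1, but it is not the title of a sample, so whether it was the first unedited library is not stated. Per the submitters' processing notes, the genome build was hg38, and the tools named were BWA 0.7.16a, Picard, SAMtools 1.17 and deepTools 3.5.4. The read minimum and version of TSScall are not given in the sources used here. Every call was an interval 1 base long, and its end coordinate was taken as the 1-based position of the call. This convention was not checked against the genome sequence. The score column, as deposited by the authors, was 0 in all 28283 calls, so the calls could not be ranked, and the number of reads behind a call and the depth of the libraries are unknown. Every identifier was of the kind that TSScall gives when no annotation is used. The smallest gap between neighbouring calls on a strand was 206 bp, and 12.4% of the gaps were at most 500 bp. Just below 254 bp, the smallest gap in the run of calls at the globin gene HBB, 30 gaps shared the same length. Only 2 gaps were shorter than that length. Whether the caller set a minimum distance between calls was not tested. The gaps and densities of calls in runs may therefore reflect the caller as well as the spacing of start sites.

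Gene positions and names were taken from the NCBI RefSeq table of assembly GRCh38.p14, which shares its primary chromosome coordinates with hg38. The table gave the outer start and end of each gene, with no strand, exons or inner transcript starts, and a genome sequence was not used here. A gene therefore counted as called when a forward call lay within 500 bp of its left end or a reverse call within 500 bp of its right end, and these calls are named promoter calls. Genes with an alternative start inside the gene were missed by this rule, and a call at the end of an oppositely oriented gene could be taken for a start. The analysis was restricted to chromosomes 1 to 22 and X, with 28159 calls, 59098 genes and 19974 protein-coding genes. Calls that were not promoter calls were named upstream antisense when a promoter call of the other strand lay 0 to 1000 bp away in the divergent orientation. The rest were split by whether they lay inside a gene. Distal calls lay over 1000 bp from both ends of every gene. A call was paired when a call of the other strand lay 0 to 1000 bp upstream of it. The plan used annotated transcript starts with their strand, so the definitions of promoter calls, and with them of called genes and offsets, of upstream antisense calls and of distal calls all depart from it, while the sizes of the windows are those planned.

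Shares are given with Wilson 95% confidence intervals. These intervals and all p-values cover counting over calls or genes, which are not independent replicates, and carry no error between libraries. Chance levels came from moving all calls by 5 kb either way and, for pairs, from 100 random shifts of the reverse calls by 5 to 50 kb. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 15 lists. The mean number of distal calls within 100 kb was tested with a two-sided permutation test of 100000 draws of genes. The lists, the windows and the rule for named genes were fixed before the data were examined. By that rule, members of the globin, erythroid transcription factor, fetal-globin regulator, haem and iron and red cell membrane lists could be named whether called or not; some members are not reported here. Further named genes were called members of the marker lists of other cell types, uncalled members of the ribosomal, cell cycle and transcription lists, and the 10 protein-coding genes with the most calls on their own strand. In genes called at 1 end, that end gave the strand, and only these genes were ranked by calls. Other names in the text were chosen after their values were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

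The scripts were tested on simulated call lists over the 19974 protein-coding genes. Of the genes simulated with a start, 100% were found, and 3.69% of the genes simulated without one were found through a neighbour. Every simulated start lay inside the 500 bp window of a gene end and on the strand of the rule, so the 100% was fixed beforehand. Genes with only an inner start were not simulated, so the share of real starts missed by the rule is not known from this test. The list test called 5 of the 5 lists simulated as enriched and 0 unchanged lists. Alternatives were other promoter and pairing windows, protein-coding genes only, merged calls, each strand alone, other backgrounds and other distances. The planned comparisons of sequence at the calls (initiator, TATA box and 10 motifs), the sequence match of the sg1617 target and the ranking of calls by value were not run, because they need a genome sequence or a value per call. The comparison of edited clones with unedited cells was not made, since the lists analysed here hold no value per library. No column of per-sample values was left out.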

Results

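PRO-seq was performed in 2 libraries of unedited HUDEP-2 cells and in 3 edited single-cell clones, each with a different small insertion or deletion at the sg1617 cut in the BCL11A enhancer. BCL11A is a repressor of the fetal globin genes, and the study compared nascent transcription before and after disruption of its erythroid enhancer. The lists of start sites analysed here came from 1 alignment and could not be divided by library, so a difference between edited and unedited cells could not be tested. They describe instead where start sites were called in HUDEP-2 cells. Whether transcription was initiated at each call was not established. There were 14124 calls on the forward and 14159 on the reverse strand. Of these, 28159 lay on chromosomes 1 to 22 and X, from 366 on chromosome 21 to 2717 on chromosome 1. The number of reads behind each call is unknown, and there are no replicates of the lists.

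The BCL11A gene (gene ID 53335) lies on hg38 chromosome 2 from 60450520 to 60553924 and is transcribed from its right-hand end, on the reverse strand. A single call was found deep inside the gene, at position 60495297. It lay on the forward strand, antisense to BCL11A, and 58627 bp from the right-hand end of the gene. The intronic erythroid enhancer of BCL11A contains a DNase-hypersensitive site that is named +58 for its distance in kilobases from the gene's start, and sg1617 is a guide against this enhancer. No reverse call accompanied the internal call, and the nearest other call on the chromosome was 55252 bp away. The exact distance between the call and the sg1617 target was not determined, because no genome sequence was used here.

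The other 10 calls within 100 kb of BCL11A were gathered around its promoter. Inside the gene, 4 reverse calls lay between 276 and 3375 bp from the right-hand end, at 60553648, 60552072, 60550908 and 60550549. A forward call at 60553878 lay 46 bp inside the gene, in the divergent position to the call at 60553648. Upstream of the gene 3 reverse and 2 forward calls followed, the farthest at 60557364, 3440 bp beyond the annotated end. No call lay within 100 kb of the left-hand end outside the gene.

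**Figure D1:**
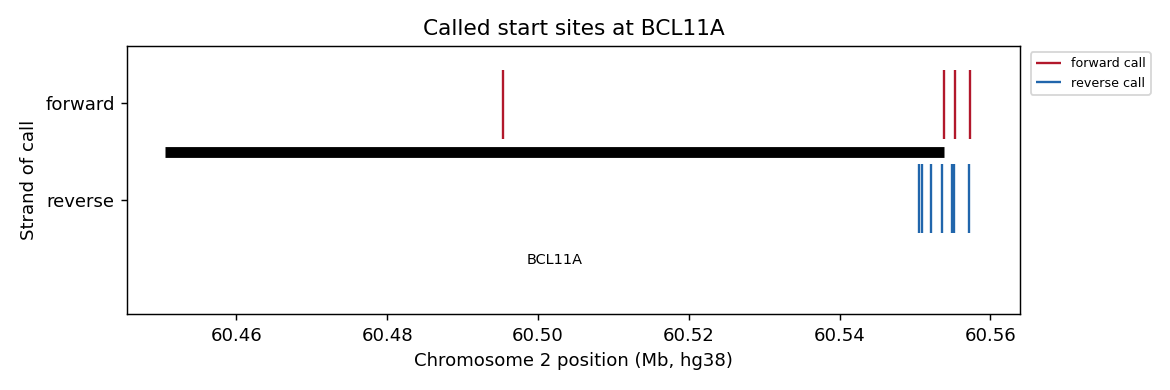
Called start sites across BCL11A, with the position on chromosome 2 in Mb (hg38) on the horizontal axis and the strand of each call on the vertical axis. The black bar is the annotated gene, red lines are forward calls and blue lines are reverse calls; the lone forward call inside the gene is at 60495297.

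Among the globin genes, those of adult haemoglobin carried calls and the fetal and embryonic genes did not. HBB, which encodes adult beta-globin, was called at the exact annotated base, 5227071 on chromosome 11, and HBD, the delta-globin gene, at 5234483, also with an offset of 0 bp. HBA2 and HBA1, the alpha-globin genes, were called at 172869 and 176673 on chromosome 16, each with an offset of -7 bp, that is, upstream. HBM was called at 165977. HBQ1 met the rule at both ends, so its orientation was not resolved by the calls. HBG1 and HBG2, which encode fetal gamma-globin, HBE1, which encodes embryonic epsilon-globin, and HBZ, which encodes embryonic zeta-globin, had 0 calls inside the gene or within 500 bp of it on either strand. HBG1 and HBG2 are nearly identical, as are HBA1 and HBA2, and reads that fit both copies cannot be placed in one of them, so the values of these 4 genes are uncertain.

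Calls continued beyond HBB, HBA1 and HBA2, whereas HBD and HBM had a single call on their own strand. HBB, 1608 bp long, held 5 reverse calls, and a further 6 lay within 2000 bp past its end, with gaps of 254 to 472 bp. HBA1 had 6 further forward calls and HBA2 had 4 within 2000 bp past their ends, with median gaps of 299 and 323 bp. The smallest gaps, 254 bp at HBB, 260 bp at HBA2 and 268 bp at HBA1, lay near the length below which gaps were rare in the lists. They may therefore not give the spacing of start sites. Outside the genes, a divergent pair lay between HBD and HBG1 in the non-coding gene BGLT3, at 5244808 on the reverse and 5244923 on the forward strand. To the right of HBE1, where the locus control region of the beta-globin cluster lies, there were 2 further divergent pairs. One was at 5275952 and 5276048, about 6.01 and 6.10 kb beyond HBE1, and the other at 5288254 and 5288334, 18.3 and 18.4 kb beyond it. NPRL3, whose introns hold enhancers of the alpha-globin genes, contained forward calls at 113791 and 120214 and a reverse call at 135726. BGLT3 and NPRL3 were named after their calls had been seen.

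**Figure D2:**
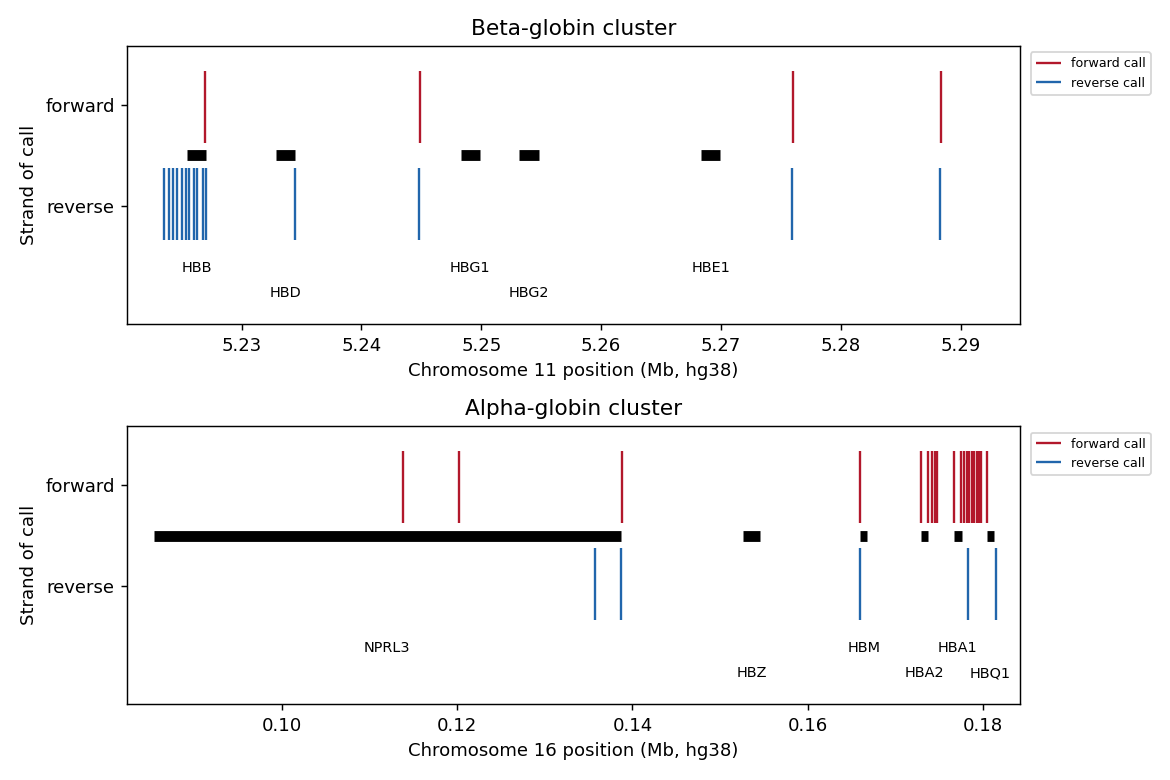
Called start sites in the beta-globin cluster on chromosome 11 (top) and the alpha-globin cluster on chromosome 16 (bottom), with the position in Mb (hg38) on the horizontal axis and the strand of each call on the vertical axis. Black bars are annotated genes, red lines forward calls and blue lines reverse calls; HBG1, HBG2, HBE1 and HBZ carry none, and runs of calls extend past HBB and HBA1.

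Gene lists fixed beforehand asked which programmes held called start sites. Of 19974 protein-coding genes, 8424 (42.2%, interval 41.5 to 42.9%) had a promoter call. After moving the calls by 5 kb, 2.79% and 2.76% did. In 13 of the 15 lists the share of called genes differed from that of all other genes at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg). Of these lists 8 were above and 5 below the other genes.

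The haem synthesis and iron list had 17 of 18 members called (adjusted p = 1.70e-05, Fisher's exact test). They included ALAS2, the erythroid first enzyme of haem synthesis, FECH, its last enzyme, TFRC, the transferrin receptor, and SLC25A37, the mitochondrial iron importer. ALAS2, TFRC and SLC25A37 were each called at an offset of -1 bp and FECH at 22 bp. SLC11A2, an iron transporter, was the member without a promoter call, with 2 calls on each strand in the gene or within 500 bp of it.

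In the red cell membrane list 19 of 25 members were called (adjusted p = 0.00155, Fisher's exact test). SLC4A1, the band 3 anion exchanger, and RHAG, the Rh-associated glycoprotein, were called at -1 bp and GYPC, glycophorin C, at -12 bp. ANK1, EPB42, GYPB, RHD, DMTN and ADD2 were not. ANK1, the erythrocyte ankyrin gene, held 20 reverse and 7 forward calls in the gene or within 500 bp of it, and ADD2 held 5 reverse calls, whereas EPB42 and RHD held 0. GYPB and GYPE are near-identical copies, as are RHD and RHCE, so their calls are uncertain. The further list of erythroid genes had 14 of 18 called (adjusted p = 0.00514, Fisher's exact test).

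The list of fetal-globin regulators had 17 of 20 members called (adjusted p = 3.66e-04, Fisher's exact test). BCL11A was called 276 bp downstream of its annotated end and ZBTB7A, another repressor of the gamma-globin genes, 121 bp downstream. CHD4, MBD2, MTA2, GATAD2A, HDAC1, HDAC2 and RBBP4, all parts of the NuRD complex that works with BCL11A, were called, as were DNMT1 and KDM1A. LIN28B, an RNA-binding protein of fetal cells, and HIC2 had 0 calls on either strand, and NFIA had 4 forward and 3 reverse calls in or near the gene but no promoter call. IGF2BP1, another RNA-binding protein of fetal cells, was called at an offset of -1 bp. The list holds activators and RNA-binding proteins as well as repressors of gamma-globin.

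The erythroid transcription factor list had 10 of 15 members called, which did not differ from other genes (66.7% against 42.2%, adjusted p = 0.0724, Fisher's exact test). GATA1 and NFE2 were called at -1 bp, LMO2 at 0 bp, MYB at 73 bp and RUNX1 at 14 bp, and KLF1 met the rule at both ends. TAL1, LDB1, GFI1B, ZFPM1 and IKZF1 were not called at an end. All 5 held calls inside the gene or within 500 bp of it, among them 11 forward calls in GFI1B and 7 in IKZF1. With any such call counted, an alternative added after the data were seen, 15 of 15 members had one (adjusted p = 2.11e-04, Fisher's exact test), and with a window of 1000 bp 12 of 15 were called (adjusted p = 0.00832). Over the alternatives run for this list, the adjusted p ranged from 2.11e-04 to 0.284 (Fisher's exact test). The globin list, with 6 of 10 called, did not differ from other genes (adjusted p = 0.339, Fisher's exact test).

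Lists of genes used by all dividing cells were called almost throughout. The ribosomal protein list had 24 of 25 members called, all but RPL15, and the cell cycle and replication list 23 of 25, all but CCND3 and ORC1. The transcription machinery list had 23 of 25, all but MED12 and PAF1. All 5 uncalled members held calls inside the gene or within 500 bp of it. The adjusted p was 2.20e-07 for the ribosomal list and 1.25e-06 for each of the other lists (Fisher's exact test). The immediate early and heat shock list had 12 of 16 called (adjusted p = 0.0116, Fisher's exact test), but 9 of 16 with a window of 100 bp (adjusted p = 0.145), and over its alternatives the adjusted p ranged from 1.52e-04 to 0.145.

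Markers of other cell types were called less often than other genes in each of the 5 lists. The lymphoid and the neuronal lists had 0 of 15 members called, which allows a share of up to 20.4% (adjusted p = 6.86e-04 for each, Fisher's exact test). With any call inside the gene or within 500 bp of it counted, a choice made after the data were seen, 4 of 15 neuronal genes (26.7%, adjusted p = 0.0464) and 1 of 15 lymphoid genes (adjusted p = 4.96e-04, Fisher's exact test) had one. Over the alternatives the adjusted p of the neuronal list ranged from 5.90e-04 to 0.0464 and that of the lymphoid list from 4.96e-04 to 0.00458. The megakaryocyte list had 0 of 10 (adjusted p = 0.00848, Fisher's exact test), but 2 of 10 members had a call inside the gene or near it, and with these counted the list did not differ from other genes (adjusted p = 0.0559, Fisher's exact test). Over the alternatives of the megakaryocyte list the adjusted p ranged from 0.00445 to 0.0559. The myeloid list had 1 of 14, CEBPA, and the hepatocyte list 1 of 15, TF, the transferrin gene, each called at -1 bp (adjusted p = 0.00848 for each, Fisher's exact test).

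**Figure D3:**
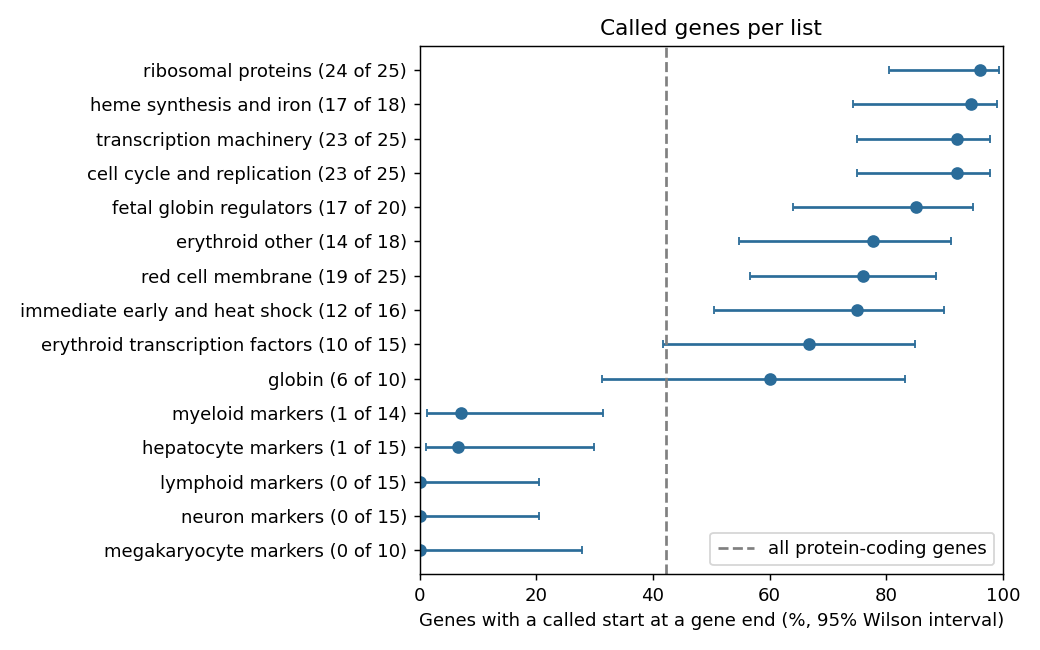
Share of genes in each of the 15 lists with a called start at a gene end, in percent on the horizontal axis, with Wilson 95% intervals as bars and the number of called members beside each list. The dashed line is the share of all protein-coding genes, 42.2%; the 5 marker lists of other cell types lie below it and the ribosomal protein list, at 96.0%, lies highest.

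Start sites at annotated genes made up 12439 of the calls, or 44.2% (interval 43.6 to 44.8%), against 4.78% and 4.47% after the calls were moved by 5 kb. Upstream antisense calls made up a further 14.2%, other calls inside genes 31.1% and other calls between genes 10.6%. Promoter calls were sharply placed: the median offset from the annotated end was 3 bp downstream, with quartiles at -1 and 41 bp. Of them 40.8% lay within 10 bp and 66.7% within 50 bp. Median offsets were 3 bp on each strand.

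Divergent pairs of calls were common. Of 14057 forward calls, 8122 (57.8%, interval 57.0 to 58.6%) had a reverse call within 1000 bp upstream, at a median distance of 176 bp (quartiles 117 and 292 bp). In 100 random shifts of the reverse calls the mean was 1.81% and the highest value 3.11%, so 0 shifts reached the observed share. Promoter calls were paired more often than distal calls. The share was 65.1% (interval 64.3 to 66.0%) of 12439 promoter calls and 37.3% (interval 36.2 to 38.3%) of 7858 distal calls, an odds ratio of 3.14. Of these distal calls 2047 lay between genes, and 32.7% of those were paired. The rest lay inside genes, where the gene table gave no inner transcript starts, so distal calls may include promoters. On the forward strand alone the odds ratio was 3.01 (p = 6.09e-155) and on the reverse strand alone 3.28 (p = 2.54e-179, Fisher's exact test, two-sided).

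**Figure D4:**
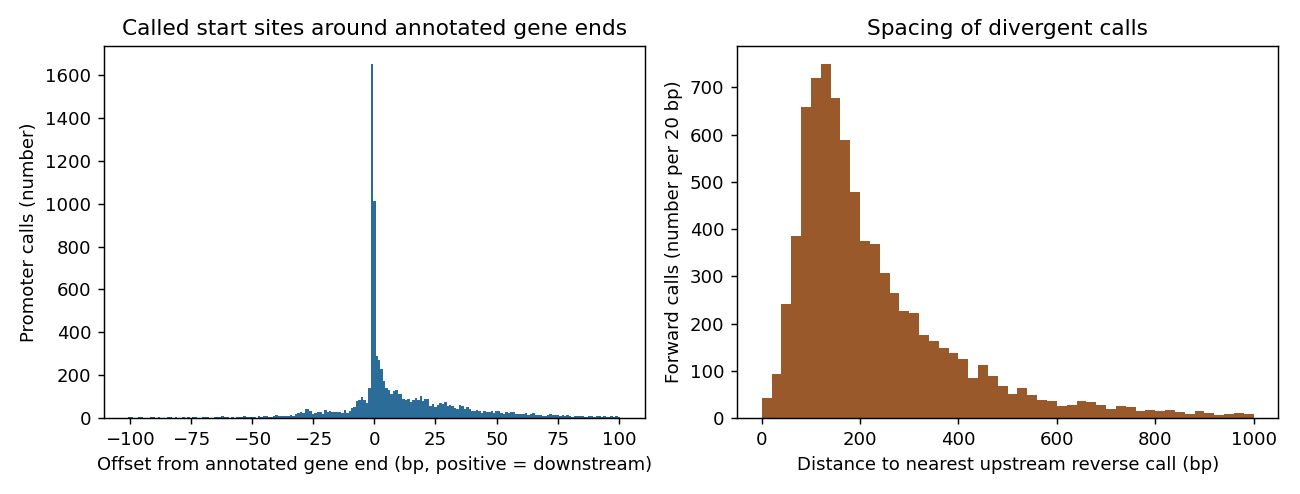
Left, number of promoter calls (vertical axis) at each offset from the nearest annotated gene end in bp (horizontal axis, positive downstream, shown from -100 to 100). Right, number of forward calls per 20 bp of distance to the nearest reverse call upstream, up to 1000 bp; the left distribution peaks at -1 and 0 bp and the right has its median at 176 bp.

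Most called genes had 1 call on their own strand, and a few carried long runs. Of 8237 genes called at 1 end, counting calls in the gene or up to 500 bp upstream, 6040 (73.3%) had 1 call, 1537 had 2, 660 had 3 or more and 119 had 5 or more. The histone gene H4C12, 387 bp long, was also called at 1 end but is not among the 8237, since its call lay past its other end; it is named after its value was seen. Among the 8237 genes, the most calls were in CA1, carbonic anhydrase 1, an abundant red cell enzyme, with 54 reverse calls in 50506 bp on chromosome 8 (85327608 to 85378113). TFRC followed with 38 in 32807 bp on chromosome 3, and then ITGA4, an integrin subunit, with 24. MYC, a transcription factor of growing cells, and RCC1, a regulator of the Ran cycle, had 18 each, PIM1, a kinase gene, 17, SLC25A37 16, PPP1R10 15, HMGB1 14 and MYB 12. Per kilobase, PIM1 had 3.22, MYC 2.39, TFRC 1.16 and CA1 1.07 calls. Genes not called at 1 end were not ranked, among them ANK1, with 20 reverse calls in the gene or within 500 bp of it. When calls within 500 bp of each other were merged, 1449 genes in place of 2197 had 2 or more calls.

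Distal calls were more frequent around erythroid genes than around other called genes. The 58 genes called at 1 end from the globin, erythroid transcription factor, haem and iron, red cell membrane and further erythroid lists had 6.48 ± 8.73 distal calls within 100 kb (SD, n = 58 genes), against 1.73 ± 2.72 for 8180 other called genes (SD, n = 8180). The permutation p was 2e-05, the smallest that 100000 draws can give. Of the 58 genes, 42 lay above the median of the others, which was 1, and the median of the erythroid genes was 3.5. The highest numbers were 48 around CA1, 39 around TFRC and 20 around SLC25A37, and they include the runs of calls inside these genes. With distal calls between genes only, the means were 1.76 and 0.429, a difference of 1.33 in place of 4.75 (permutation p = 2e-05). The difference was 0.388 for those over 5000 bp from any gene end (permutation p = 0.00388), and with calls within 1000 bp counted as 1 the difference was 2.80 (permutation p = 2e-05). Neighbouring genes such as HBA1 and HBA2, or CA1 and CA2, share distal calls and are not independent.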

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

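The mitochondrial genome was not part of the comparisons and carried 94 calls, 49 on the forward and 45 on the reverse strand, with 37 annotated genes. These calls were singled out because they are a signal outside the data used in the comparisons, and they were not tested. The density was 5.87 calls per kb of the span of annotated genes, against 9.29 calls per Mb on chromosomes 1 to 22 and X.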

How the results depend on the processing

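The share of calls at annotated promoters moved from 44.2% to 32.9% with a window of 100 bp, 52.9% with 1000 bp and 33.8% with protein-coding genes only. The share of protein-coding genes with a call moved from 42.2% to 37.1% with 100 bp, 44.8% with 1000 bp and 53.7% with any call inside the gene, and was 21.7% from forward and 21.4% from reverse calls alone. Divergent pairs moved from 57.8% to 53.4% with a window of 500 bp, 59.6% with 2000 bp and 52.4% with calls within 500 bp merged. Genes with 2 or more calls fell to 1449 with the same merging. Between 12 and 14 of the 15 lists passed the threshold under each alternative run. Of the 60 list results under alternatives, 56 kept their direction and side of the threshold, 2 lost and 2 gained it. The median offset stayed between 1 and 4 bp. The odds ratio of pairing stayed between 2.89 and 3.33, and the difference in distal calls around erythroid genes lay between 1.33 and 5.86, except for calls between genes over 5000 bp from any gene end, where it was 0.388 (permutation p = 0.00388). Merging calls within 100 bp removed 0 calls and tests nothing. Merging at 500 bp, counting any call inside a gene, leaving out CA1 and TFRC, leaving out calls inside genes with 5 or more calls, counting distal calls within 1000 bp as 1 and restricting distal calls to those between genes were chosen after seeing the data. Calls without a stated number of reads cannot be weighed by depth, so a gene without a call may have been transcribed below the caller's threshold. The alternatives for the initiator, TATA box and motif comparisons were not run, as these comparisons need a genome sequence that was not used here, and neither was the restriction to calls with the higher value, since every score was 0. The cause of the moved values was not tested beyond the construction of each alternative. No paired analysis was possible because the lists hold no value per library.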

Other observations

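The gene classes and families described here were chosen after the calls had been seen, the families from a wider set of name prefixes whose shares had been looked at. Of 443 transfer RNA genes, which are transcribed by RNA polymerase III, 269 (60.7%, interval 56.1 to 65.2%) had a call at an end, against 7.34% with the calls moved by 5 kb, and 260 had one within 100 bp. Small nuclear RNA genes had 44 of 154 called (28.6%), small nucleolar RNA genes 167 of 1196 (14.0%), long non-coding RNA genes 9.61% of 18177, and pseudogenes 1.21% of 15212, which is close to the 0.966% of moved calls. Transcribed pseudogenes, a separate class, had 164 of 1246 called (13.2%), against 1.24% with moved calls. Among protein-coding families, 73 of 77 mitochondrial ribosomal protein genes (94.8%), 58 of 70 clustered histone genes (82.9%), 38 of 46 genes of the NDUF family of respiratory complex I (82.6%) and 41 of 50 proteasome subunit genes (82.0%) were called. The zinc finger genes named ZNF had 307 of 517 called (59.4%). Olfactory receptor genes had 0 of 392 called, keratin-associated protein genes 0 of 94, protocadherin genes 0 of 65, collagen genes 2 of 44 and interleukin genes 2 of 36. Since these families were picked for their shares, no test is given for them. Many of these genes lie in arrays of near copies, so single members are uncertain.

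In the paragraphs below, the tests of the 2 parts of the runs and those without single genes or CA1 and TFRC together, the test with distal calls between genes and both tests on chromosome 6, whose region was picked from its calls, were chosen after the results were seen. For the surplus of distal calls around erythroid genes, calls inside the transcribed genes did not account for all of it, since the difference was 1.33 calls per gene with calls between genes only (permutation p = 2e-05). Run-on within 5000 bp of gene ends did not either. With calls between genes and over 5000 bp from any gene end the difference was 0.388 (0.552 against 0.164 per gene, permutation p = 0.00388). Of the 58 erythroid genes 17 had such a call, against 8.58% of the others. Run-on reaching beyond 5000 bp was not tested. The 70 called genes of the ribosomal, cell cycle and transcription lists did not show it. The erythroid genes exceeded them by 1.43 calls per gene (1.76 against 0.329, permutation p = 2e-05), and the 24 ribosomal protein genes by 1.38 (permutation p = 0.00162). These comparisons with the ribosomal, cell cycle and transcription lists were not matched on neighbouring genes, so they cannot tell whether such genes in similar surroundings share the surplus. Over all distal calls, draws of called genes matched on the number of protein-coding genes within 100 kb were made as planned. The difference was then 4.65 (6.48 against 1.84 per gene, permutation p = 2e-05), so the number of neighbouring genes did not account for it. The matched draws counted calls inside genes too. Transcription levels could not be matched, start sites missing from the gene table may be among the calls, and a link to lineage enhancers was not tested, so what these calls are stays open.

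Runs of calls along genes may come from dense signal along strongly transcribed genes or from separate start sites. Over the 119 genes with 5 or more calls, calls over 1000 bp from the gene's ends had an opposite-strand call upstream in 32.0% of 556, against 37.7% of other distal calls (p = 0.00732), but the share was 35.1% without CA1 (p = 0.255) and 34.0% without TFRC (p = 0.102, Fisher's exact test), so this difference rested on these genes. In the 10 genes with most calls the share was 10.5% of 191 (interval 6.88 to 15.6%, p = 5.62e-17, Fisher's exact test). Without CA1 and TFRC, which had 0 of 49 and 0 of 33, it was 18.3% of 109 (p = 2.19e-05, Fisher's exact test). MYB, with 5 of 10, did not have the low share. These 10 genes were ranked by the same calls on 1 strand, which can favour runs with few opposite-strand calls. Calls of 1 gene are also not independent, so the p-values overstate the evidence. The low share in these genes therefore does not decide between the sources, and dense signal stays a candidate. In the other 109 genes the share was 43.3% of 365 (interval 38.3 to 48.4%, p = 0.0357, Fisher's exact test), and between 42.7 and 44.0% without any 1 gene. Removing any 1 of 26 genes ended the call (highest p = 0.0592, Fisher's exact test). This was not the low share that dense signal would need, but the sets compared were not alike. The calls in the runs were kept by distance from their own gene's ends only, whereas other distal calls lay over 1000 bp from every gene's ends. Calls in the runs could thus lie near the end of another gene, where promoter calls were paired more often, which can raise their share. The source in these genes stays open. Of the 119 genes, 33.6% also had a call on their strand within 2000 bp past the far end, against 5.75% of genes with 1 call (p = 9.93e-20, Fisher's exact test).

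Chromosome 6 had 2.07 calls per protein-coding gene, the highest of the chromosomes, and chromosome X the lowest, 0.746. The region from 26 to 29 Mb of chromosome 6 held 463 calls, where 53 of 61 clustered histone genes and 100 of 144 transfer RNA genes were called. Without it the chromosome had 1.78 calls per gene (counting interval 1.70 to 1.86), and the highest other autosome, chromosome 18, had 1.85. The share of genes called outside the region was 44.2%, against 42.6% in the other autosomes (p = 0.349, Fisher's exact test). Removing a region picked for its calls had to lower the value, so how far the gene clusters account for the surplus stays open.

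The numbers in the call identifiers ran against the coordinate in 5.02% of steps on the forward and 8.04% on the reverse strand. In 126 clusters of 3 or more calls whose call at an annotated start was neither first nor last by position, that call had the lowest number in 43 and the highest in 11. Random order gives 36.6 clusters for the lowest number (exact p = 0.241, two-sided), and numbers in coordinate order would give 0. Random order is a poor reference for numbers that mostly follow the coordinate, so whether they also follow the strength of a call stays open, and they were not used as ranks. More promoter calls lay at an offset of -1 bp (1652) than at 0 bp (1010).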
